A study of Homo sapiens with 12 samples.

How the data were processed

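Total RNA of 12 cultures of PMA-treated THP-1 cells, 6 unpolarized (M0) and 6 polarized with IL-4 and IL-13 (M2), was amplified and labelled with Cy3 in 1 colour, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Each deposited file holds 1 array of 61184 spots. The intensity values (processed signal, median signal and local background) were extracted with Agilent Feature Extraction 11.0.1.1 under the protocol GE1_1100_Jul11 from scans on a G2505C scanner, per the file headers; the labels name another scanner model. The processed signal had been background-subtracted and spatially detrended within each array, and nothing was scaled between arrays, per the file headers. The submitters' processing notes name Agilent Feature Extraction without a version. The processed signal of M0 replicate 1 alone was deposited rounded to 3 significant digits (100% of its values); this rounding changes a value by less than the spread between spots. The scan runs were read from the headers and numbered 1 to 3.

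Of the spots, 1439 control spots and 600 spots of 60 blank probes were left out, as were spots marked by Feature Extraction as non-uniform or as population outliers, between 14 and 66 per array. The log2 values of the spots of 1 probe were averaged, which left 58965 probes. From the log2 processed signal the 75th percentile over these probes was subtracted on each array. That percentile was between 83.0 and 198.1 intensity units. A probe was tested if it was well above background on at least 6 of the 12 arrays, which 33983 probes were (57.6%), and 173 of these had a value left out on some array. M2 was compared with M0 in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the probes tested. A probe was called at an adjusted p under 0.05, and at 2-fold if the log2 fold change was also 1 or more in size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

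The fit was tested on simulated values for the same comparison, with 33810 probes of which 200 were changed. With independent arrays it recovered 2% of the probes changed by 0.5 on the log2 scale, 28% at 1, 88% at 2 and 96% at 3, and 10.1% of its calls were false. With shifts between scans added, it recovered 2%, 36%, 80% and 92%, with 5.4% of its calls false. With these shifts and the scan as a block, it recovered 2%, 46%, 86% and 86%, with 6.8% false. In the data a far larger share was called, 25.4% of the probes tested. No arrays were simulated as repeats of the same preparation. These rates therefore do not give the power or the false calls of the fit to the data.

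Gene names were taken from a RefSeq table of assembly GRCh38.p14, matched without accession versions. The 20 probes that carry a RefSeq accession, with 10 spots each, all matched 1 symbol; 2 of these genes are not reported here. The other 58945 probes (99.97%) carry an ID of the array maker that is in none of the tables used here. Since the headers name hg19, no coordinates are given. The rule fixed beforehand named genes with a symbol that were called, did not overlap between groups and were well above background throughout the brighter group, which only PRMT1 and DYNLL1 met, and called members of 27 fixed gene lists, which were PGK1, GAPDH and RPS18. None of the 14 genes to be given in any case had a named probe. The remaining ones of the 18 genes were chosen after it was seen that no others could be named. Of 824 genes in the lists 5 had a named probe, and a list needed 5 members for a test, so the planned tests of lists were not made. No column marks a probe as coding or non-coding, so non-coding RNAs were not counted apart. The 4 probe IDs printed follow the same rule without the need for a symbol.

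The alternatives planned before the data were examined were quantile normalization, scaling to the median, no filter or a stricter filter on dim probes (well above background on all 6 arrays of a group), a replicate block, array weights, a variance trend with robust estimation, the scan as a fixed block, and leaving out each array in turn. Added later were cyclic loess, normexp background correction (offset 50) on the median signal since the files have no mean signal, the scan as a random block, each of scans 1 and 3 alone, leaving out scan 2, averaging arrays that are nearly alike, and leaving out M0 replicates 1 and 3. Single array measures were compared by exact permutation tests. The precision is set by 6 arrays per group, whose p-values measure the spread between the arrays as labelled.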

Results

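The transcriptome of THP-1 cells, a human line grown from monocytic leukaemia, was measured in 2 macrophage states with 6 arrays each. Unpolarized macrophages (M0) were obtained with 100 ng/ml of the phorbol ester PMA over 2 days and a further 72 hours without it. Alternatively activated macrophages (M2) were obtained from such cells by 24 hours with IL-4 and IL-13, at 20 ng/ml. The labels do not state whether M0 cells spent these 24 hours in culture as well. Each preparation was hybridised to a 1-colour oligonucleotide array that holds probes for long non-coding and messenger RNAs. The labels describe the preparations of a group as independent. Between 36.8% and 68.2% of the 58965 distinct probes were well above background on an array, and no spot was saturated. The number of arrays limits the precision of every value given here.

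The comparison addressed which messenger and long non-coding RNAs differ in abundance between M2 and M0 macrophages. Genes could be named only for the few probes that carry a RefSeq accession, and most of the 18 genes given here are widely expressed. Of these 18 genes, 6 fell in M2 macrophages and none rose, by limma on signals scaled to the 75th percentile of each array. The largest decreases among them were those of phosphoglycerate kinase 1 (PGK1) and the arginine methyltransferase PRMT1, at 2.19-fold and 1.86-fold lower in M2. Of the other 12, 11 were lower and 1 was higher in M2 without passing the test. The size of these changes, and for some genes the direction, depended on the scaling. After quantile normalization 2 of the 18 genes were called, namely PGK1 and PRMT1. After cyclic loess 6 genes were lower and 12 higher, with 1 called lower and 1 higher. With arrays that are nearly alike averaged, none of the 18 was called. Normexp background correction called 11, all lower in M2, and array weights called 17, of which 16 were lower and 1 higher.

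PGK1 (NM_000291), a glycolytic enzyme that makes ATP, had a log2 signal of 3.02 ± 0.30 above the 75th percentile in M0 and 1.89 ± 0.62 in M2 macrophages (SD, n = 6 each). Its log2 fold change was −1.13 (SE 0.27, limma adjusted p = 0.0078), or 2.19-fold lower in M2. It was −0.96 after quantile normalization (adjusted p = 0.015) and −0.95 after cyclic loess (adjusted p = 0.012). PRMT1 (NM_001536), which places asymmetric methyl groups on arginines of histones and other proteins, fell from 6.48 ± 0.28 to 5.58 ± 0.37 (SD, n = 6 each). Its log2 fold change of −0.89 (SE 0.21, limma adjusted p = 0.0061) was −0.53 after quantile normalization (adjusted p = 0.037) and −0.47 after cyclic loess, where it no longer passed (adjusted p = 0.059). The signals of PRMT1 in the 6 M2 arrays all lay below those of the 6 M0 arrays. The same held for DYNLL1 (NM_003746), a light chain of the dynein motor, which fell by 0.75 on the log2 scale (SE 0.17, limma adjusted p = 0.0069). DYNLL1 did not pass the threshold after quantile normalization (adjusted p = 0.077) or cyclic loess (adjusted p = 0.49). The calls of PGK1, PRMT1 and DYNLL1 held in each of the 12 fits that left out 1 array, but such a fit keeps the partners of arrays that are nearly alike. With the alike arrays averaged to 3 M0 and 4 M2 units, none of the 3 was called, at log2 fold changes of −0.87, −0.74 and −0.66 (SE 0.38, 0.31 and 0.28, adjusted p = 0.25, 0.24 and 0.24).

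**Figure D1:**
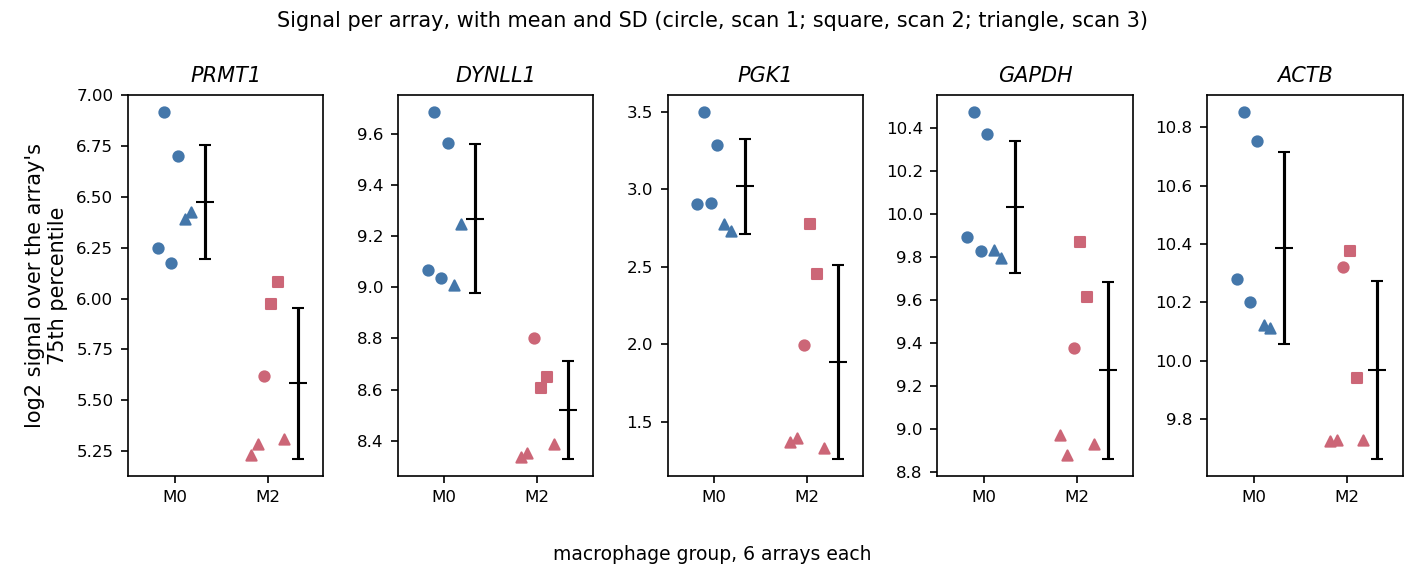
Log2 signal over the 75th percentile of the array for PRMT1, DYNLL1, PGK1, GAPDH and ACTB on each of the 6 M0 and 6 M2 arrays. Bars show the mean and SD of a group, and circles, squares and triangles stand for scans 1, 2 and 3. The 6 M2 values of PRMT1 and DYNLL1 lie below the 6 M0 values, while the groups overlap for the other genes.

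Among the gene lists fixed beforehand, 3 had members with a named probe. The 2 named members of the 24 glycolysis genes both fell. They were PGK1 and GAPDH (NM_002046), the enzyme of the step before it, with a log2 fold change of −0.76 for GAPDH (SE 0.22, limma adjusted p = 0.021). Both also passed when adjusted over the list alone, which here means over 2 genes. GAPDH did not pass after quantile normalization, at −0.34 (adjusted p = 0.084), or after cyclic loess, at −0.11 (adjusted p = 0.61). Of the 43 ribosomal protein genes, RPS18 (NM_022551) fell by 0.52 on the log2 scale (SE 0.18, limma adjusted p = 0.0498), and RPLP1 (NM_001003) was at −0.42 (SE 0.18, limma adjusted p = 0.099). Adjusted over the list alone, again over 2 genes, they were at 0.025 and 0.033, of which the latter is the unadjusted p of RPLP1. RPS18 did not pass after quantile normalization, at −0.15 (adjusted p = 0.42). After cyclic loess RPS18 was at 0.14 and RPLP1 at 0.25, on the other side of 0. The single named gene of oxidative phosphorylation, COX4I1 of cytochrome c oxidase, was at −0.46 (SE 0.20, limma adjusted p = 0.11), had 0.036 when adjusted over the list alone, which for a single gene is its unadjusted p, and was at 0.19 after cyclic loess. With array weights RPLP1 and COX4I1 were called lower in M2 (adjusted p = 0.0072 and 0.0019). With arrays that are nearly alike averaged, none of these named members was called. GAPDH was then at −0.59 and RPS18 at −0.45 (adjusted p = 0.36 and 0.44). With at most 2 named members, no list could be tested as a set.

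Genes of chromatin, the cytoskeleton and translation made up most of the rest. H3-3A, which encodes histone H3.3, fell by 0.55 on the log2 scale (SE 0.17, limma adjusted p = 0.026). It did not pass after quantile normalization (adjusted p = 0.65), and after cyclic loess it was at 0.074. With arrays that are nearly alike averaged, H3-3A was at −0.49 (SE 0.29, adjusted p = 0.39). The actin genes ACTB and ACTG1 were at −0.42 and −0.36 (SE 0.20 and 0.18, limma adjusted p = 0.14 and 0.16), and the actin-binding PFN1 was at −0.39 (SE 0.17, adjusted p = 0.11). After cyclic loess ACTB, ACTG1 and PFN1 were at 0.26, 0.30 and 0.28. ARHGDIA was at −0.56 (SE 0.27, adjusted p = 0.14), and ODC1, which starts polyamine synthesis, at −0.45 (SE 0.36, adjusted p = 0.38). RPL10 and RACK1, both parts of the ribosome, were at −0.29 and −0.35 (adjusted p = 0.21 and 0.26). The RPL10 probe was far dimmer, with a log2 signal of 0.05 in M0 against 9.65 for RACK1 and 10.11 for RPS18. The mitochondrial import gene MTX1 and the translation initiation gene EIF3D were at −0.14 and −0.06 (adjusted p = 0.79 and 0.84). EIF3D passed the threshold in the other direction after cyclic loess, at 0.48 (adjusted p = 0.014). The glutamate receptor gene GRM4, near background with 4 M0 and 5 M2 arrays well above it, was at 0.50 (SE 0.23, adjusted p = 0.14). With array weights GRM4 was called higher (0.45, adjusted p = 0.031), and H3-3A, ACTB, ACTG1, PFN1, ARHGDIA, ODC1, RPL10, RACK1 and MTX1 were called lower in M2. That fit counts each array as a replicate. With arrays that are nearly alike averaged, none of the 18 genes was called. Probes for ACTB, ACTG1, GAPDH, H3-3A and the ribosomal protein genes are uncertain in that close gene copies or pseudogenes share much of their sequence.

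**Figure D2:**
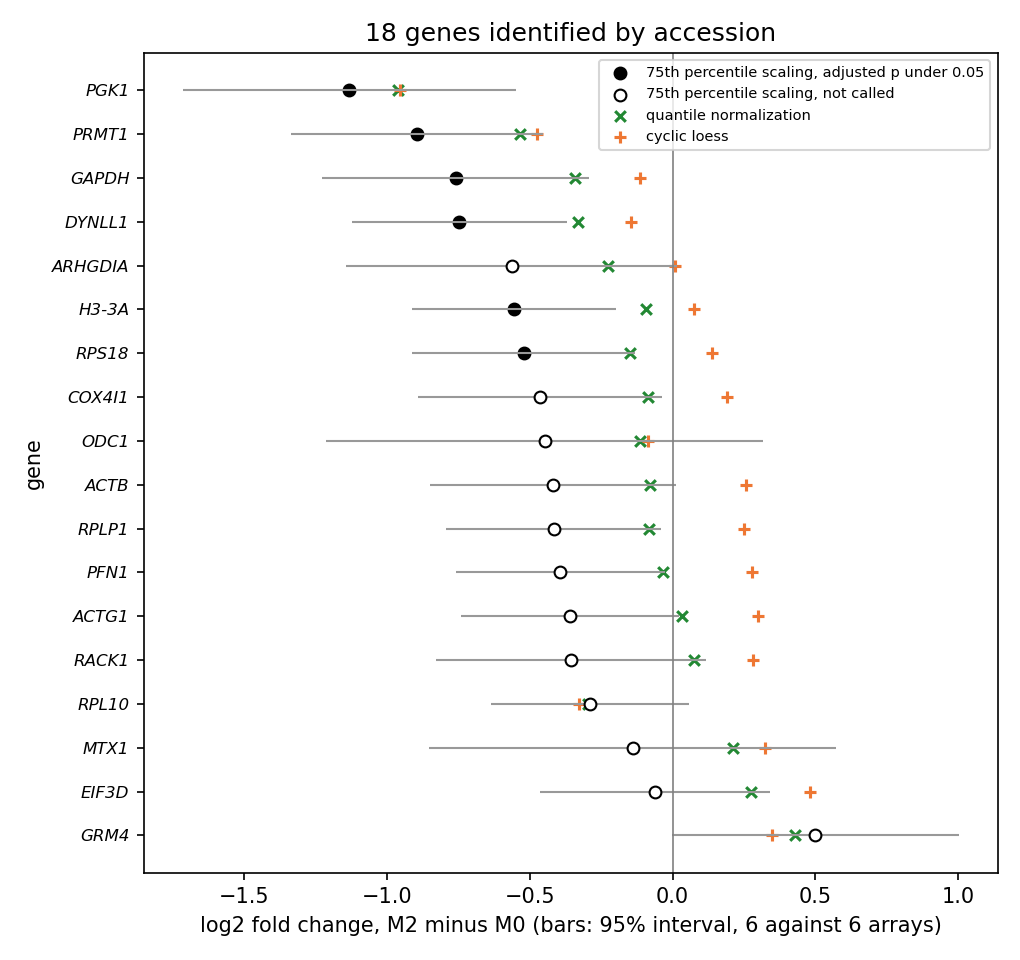
Log2 fold change of M2 over M0 macrophages for 18 genes with an accession. Circles show the 75th percentile scaling with 95% intervals from limma (filled, adjusted p under 0.05), crosses quantile normalization and plus signs cyclic loess; 17 of the 18 circles lie below 0, against 13 of the crosses and 6 of the plus signs.

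These changes accompanied a difference in the shape of the signal distributions. The log2 distance between the 95th and the 75th percentile was 3.95 ± 0.14 on M0 and 3.65 ± 0.12 on M2 arrays (SD, n = 6 each; exact permutation test, two-sided, p = 0.0108, adjusted p = 0.0433 over the 4 array measures tested). The M2 mean was lower by 0.294, and the difference was −0.23 within scan 1 and −0.22 within scan 3. The permutation test takes all 12 arrays as independent. If arrays that are nearly alike are repeats, its p is too small. Probes over 8 on the log2 scale above the 75th percentile, 198 in all, had a median log2 fold change of −0.47, whereas the 6996 tested probes lowest in signal had a median of 0.15. After quantile normalization these medians were −0.09 and 0.03. The number of probes well above background was 31916.5 ± 4458 on M0 and 33955 ± 7093 on M2 arrays (SD, n = 6 each; exact permutation test, two-sided, p = 0.565), within scan 1 higher by 1821 and within scan 3 higher by 4221 in M2.

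Across all 33983 probes tested, 8644 (25.4%) differed between M2 and M0 macrophages at a limma adjusted p under 0.05, of which 3322 were higher and 5322 lower in M2. The count was 17474 with array weights, 1102 with arrays that are nearly alike averaged and 98 with those alike across scans averaged too. A change of at least 2-fold was called for 4105 probes, 1251 higher and 2854 lower. By the fitted folds, 45 probes were higher and 72 lower at 16-fold or more, and 18 and 22 at 32-fold or more. These folds are uncertain where a group has arrays not well above background. With every signal raised at least to the lowest that was well above background on its array, the called probes were 941 higher and 2637 lower at 2-fold or more, 33 and 47 at 16-fold or more, and 10 and 18 at 32-fold or more. The M0 and M2 signals did not overlap for 4648 probes (13.7% of those tested), and for 69.1% of those called at 2-fold or more. Chance gives 0.216% only if all 12 arrays are independent, and more if arrays that are nearly alike are repeats. Among the probes called at 2-fold or more, 21 were not well above background on any M0 array and 36 on any M2 array.

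**Figure D3:**
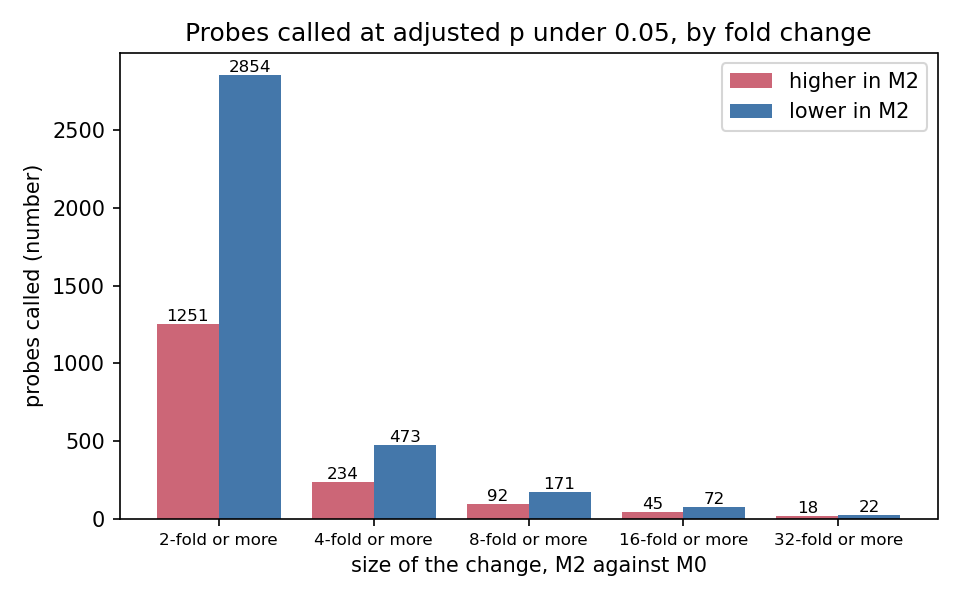
Number of probes called at a limma adjusted p under 0.05 (vertical axis) by the least size of their fitted fold change between M2 and M0 macrophages (horizontal axis), higher and lower in M2. At 2-fold or more 1251 probes are higher and 2854 lower, and at 32-fold or more 18 and 22.

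The probes at both ends of the ranking carry the array maker's ID alone, which the tables used here do not pair with a gene. ASHGA5P000619 was the most induced, with a log2 signal of 7.13 ± 1.85 in M2 (SD, n = 6). It was not well above background on any M0 array, so that M2 was at least 888-fold higher (limma adjusted p = 3.3e-07), taking for each M0 array the higher of the probe's own signal and the lowest signal that was well above background. ASHGA5P031820 was also higher in M2 (limma adjusted p = 9.3e-06), but well above background on only 3 of 6 M0 arrays. Its fitted fold is therefore uncertain, and it was 85.0-fold with the M0 arrays taken in the same way. Among the largest decreases, ASHGA5P001654 was well above background on 1 of 6 M2 arrays and 44.8-fold lower with the M2 arrays taken in this way (limma adjusted p = 3.8e-07), and ASHGA5P011081 had a log2 fold change of −5.95 (SE 0.41, limma adjusted p = 4.6e-07), and was well above background on all 12 arrays.

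The arrays had been scanned in 3 runs, in which the groups were unevenly spread. Scan 1 held M0 replicates 1 to 4 and M2 replicate 3, scan 2 held M2 replicates 4 and 5, and scan 3 held M0 replicates 5 and 6 with M2 replicates 1, 2 and 6. With the scan as a block, 8831 probes were called and 4198 at 2-fold or more, and 6408 of the 8644 calls were shared. Scan 2 held no M0 array, so M2 replicates 4 and 5 added nothing to the difference between groups in this fit. Within scan 3 alone 13362 probes were called, and within scan 1, where M2 had 1 array, 307. With the scan as a block the call of RPS18 was lost, at −0.38 (SE 0.17, adjusted p = 0.14) against −0.52 (SE 0.18) without the block, while ARHGDIA (−0.69, adjusted p = 0.0023), MTX1 (−0.51, adjusted p = 0.021) and ODC1 (−0.78, adjusted p = 0.028) gained one. These 3 genes were also called when scan 2 was left out, at −0.93, −0.67 and −0.97 (limma adjusted p = 0.0050, 0.016 and 0.0087). With the scan as a random block only ARHGDIA of these 3 was called (adjusted p = 0.023). MTX1 was then at −0.35 and ODC1 at −0.63 (adjusted p = 0.30 and 0.11). Within scan 3, 15 of the 18 named genes were called, all lower in M2. The arrays of scan 3 were nearly alike within each group. Within scan 1, with 1 M2 array, none of the 18 was called, and PGK1 was at −1.15 and PRMT1 at −0.89 (adjusted p = 0.17 and 0.30).

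The first principal component, with 39.9% of the variance, separated the groups, from −112.9 to −48.7 for the M0 and from 37.1 to 99.4 for the M2 arrays. The second, with 18.9%, set M2 replicates 4 and 5 of scan 2 (−106.4 and −92.8) apart from the other arrays, which lay between −21.9 and 68.4.

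**Figure D4:**
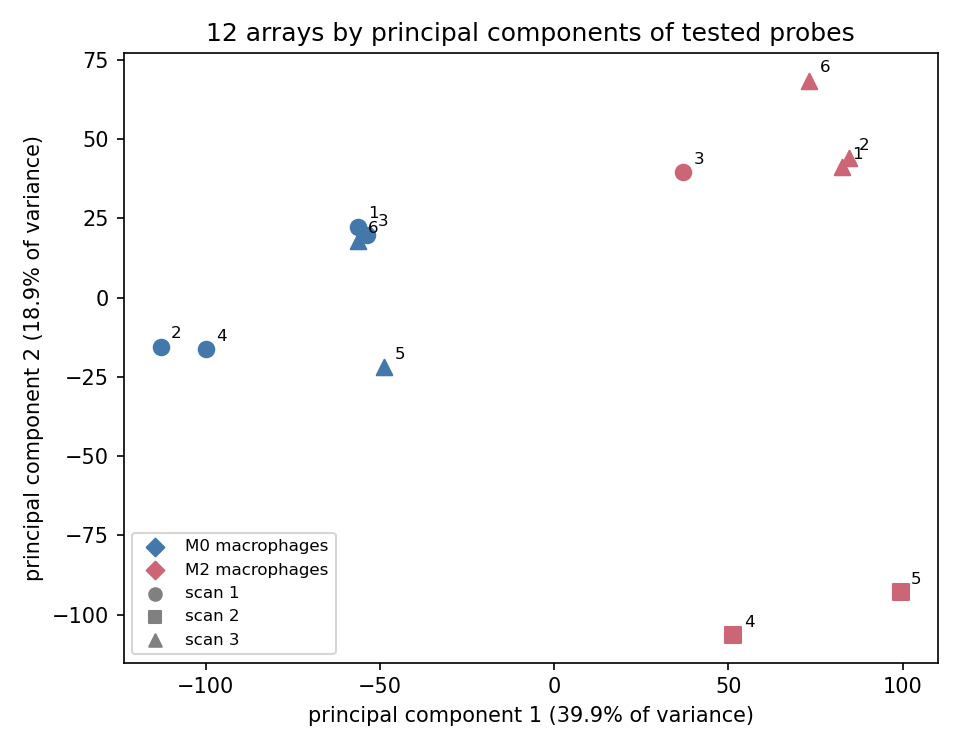
Scores of the 12 arrays on the first 2 principal components of the tested probes (axes in log2 units, with their share of the variance). Colours give the group, symbols the scan and numbers the replicate; M0 arrays lie at −48.7 or below and M2 arrays at 37.1 or above on the first component.

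Some arrays of a group were nearly alike. Over 6430 bright probes, the robust SD of the log2 difference was 0.106 to 0.150 for 6 pairs (M0 replicates 1 and 3, 2 and 4, 5 and 6, and the pairs among M2 replicates 1, 2 and 6), against 0.271 to 0.776 for the other pairs of a group. Each array was kept as 1 replicate, since the labels describe the preparations as independent. If such arrays were repeats of 1 preparation, the p-values here would be too small. With the alike arrays averaged, 3 M0 and 4 M2 units gave 1102 calls, all of at least 2-fold and all among the 8644, and none of the 18 named genes, whose folds are given for PGK1, PRMT1 and DYNLL1 above. With those also alike across scans averaged, 2 M0 and 3 M2 units gave 98.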

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

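The flags below follow rules set before the data were examined. Of 44 groups of 6 arrays examined for a value far from the rest, 2 had one, where chance gives about 2.2. RPLP1 on M2 replicate 3 had a log2 signal of 10.15, against 9.69 to 9.83 on the other M2 arrays, a gap of 0.709 of the range of the group. The log2 distance between the 75th percentile and the median was 2.01 on M2 replicate 5, against 2.22 to 2.32 on the other M2 arrays, a gap of 0.670 of the range. In the control spots, which entered no comparison, 1 of the 12 probes for ERCC spike-in RNAs (ERCC-00062_278) was well above background on all 12 arrays, with a median signal of 174 to 458. The labels mention no spike-in, and 3 of the 12 ERCC probes were well above background on no array.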

How the results depend on the processing

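The alternatives with cyclic loess, normexp, a random scan block, single scans, averaged arrays, and without scan 2 or M0 replicates 1 and 3 were chosen after seeing the data. The count of 8644 calls stayed within 1.5 times in all alternatives except array weights (17474, and 6597 against 4105 at 2-fold or more), scan 1 alone (307 and 307), scan 3 alone (13362), arrays that are nearly alike averaged (1102 and 1102) and the same across scans (98 and 98). Normexp gave 2014 at 2-fold or more, of which 434 were higher; it also took another signal column, and the cause was not tested. Averaging and scan 1 alone leave fewer replicates; for array weights and scan 3 alone the cause was not tested. Leaving out 1 array gave 6311 to 9877 calls, and 3336 to 4750 at 2-fold or more. Of the 8644, 99.77% of those tested kept their direction within scan 1 and more in every other alternative, but fewer kept their call (6408 with the scan block, 7583 after quantile normalization). The replicate block gave 8676 calls and 4263 at 2-fold or more. Under it 5 of the 18 named genes were called, and RPS18 was not (adjusted p = 0.081). Same-numbered arrays did not deviate together throughout, with correlations from −0.34 to 0.44, of which 4 were over 0.1. Of the 6 M0 arrays, 2 were closest to their own number. These 2, replicates 3 and 6, share a scan with the M2 array of their number. The scan was not removed here, so whether the numbers pair the arrays stays open.

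H3-3A, GAPDH and RPS18 lost their call without M0 replicate 2, M0 replicate 4, M2 replicate 1 or M2 replicate 2, with adjusted p up to 0.064, 0.054 and 0.12; H3-3A also without M2 replicate 6, and RPS18 without any of 8 arrays. ARHGDIA gained one without M2 replicate 4 (0.041).

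These log2 fold changes turned direction, for causes that were not tested. After cyclic loess they were 0.32 for MTX1, 0.07 for H3-3A, 0.48 for EIF3D, 0.25 for RPLP1, 0.26 for ACTB, 0.28 for RACK1, 0.14 for RPS18, 0.0098 for ARHGDIA, 0.19 for COX4I1, 0.28 for PFN1 and 0.30 for ACTG1. After quantile normalization MTX1 was at 0.21, EIF3D at 0.28, RACK1 at 0.074 and ACTG1 at 0.033. With alike arrays averaged MTX1 was at 0.19 and EIF3D at 0.047, and across scans MTX1 at 0.41, EIF3D at 0.066 and ODC1 at 0.15. With the scan as a fixed block EIF3D was at 0.014 and GRM4 at −0.00066, with a random block EIF3D at 0.0059, in scan 1 EIF3D at 0.14, and in scan 3 GRM4 at −0.027. Without 1 array, MTX1 ranged from −0.36 to 0.011 and EIF3D from −0.13 to 0.031.

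The planned normexp on mean signals and the alternatives for several probes of a gene were not run, since the files have no mean signal and no symbol has more than 1 probe; counts of non-coding genes and lists gave no value. Dim probes limit the folds, and 24982 probes were below the filter. Without it 58965 probes were tested and 6314 called; H3-3A, GAPDH and RPS18 kept their folds (−0.55, −0.76 and −0.52) with a larger SE (0.19, 0.24 and 0.20) and lost their call (adjusted p = 0.084, 0.058 and 0.13).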

Other observations

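The signals of MTX1 and ODC1 differed within the M2 group by scan. MTX1 had log2 signals of 7.65 and 7.73 on M2 replicates 4 and 5 (scan 2), above the highest M0 array (7.11), and of 5.87 to 6.06 on M2 replicates 1, 2 and 6 (scan 3), below the lowest M0 array (6.54). ODC1 was at 5.66 and 6.28 on M2 replicates 4 and 5 and at 4.16 to 4.26 on M2 replicates 1, 2 and 6, with M0 between 5.04 and 5.93. Scan 2 held no M0 array, so no difference from M0 can be had within it.

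The change from M0 to M2 was compared between scan 1, which held only 1 M2 array, and scan 3. Across 33937 probes, which are not independent replicates, 79.7% changed in the same direction in both scans, and the fold changes had a Pearson correlation of 0.83 and a Spearman correlation of 0.78. Some arrays were alike across these scans, with a robust SD of 0.271 for M2 replicates 3 and 6 and 0.287 for M0 replicates 2 and 6. If such arrays are repeats, the 2 scans are not independent. With the group in the fit, 12379 probes differed between scans.

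Chance in the grouping of arrays was tested with 100 of the 462 splits of the 12 arrays into 6 and 6, the real one included. For the probes called, 1 of the 100 splits, the real one, gave as many as 8644, and the highest of the others gave 7062. For those called at 2-fold or more, 1 of the 100 reached 4105, and the highest other gave 2254. The highest other split set the 5 arrays of scan 1 and M0 replicate 6 against the rest, so it followed the scan in part. With the scan as a block, of the 50 splits that keep each scan's numbers of M0 and M2, 1 gave as many as the real 8831 probes and 1 as many as the 4198 at 2-fold or more, and the highest of the others gave 0 for both. With the alike arrays averaged, of the 35 splits of the 7 units into 3 and 4, 1 gave as many as the real 1102 probes, all at 2-fold or more, and the highest other gave 3. In none of these tests did another of the splits tried reach the real count. The 50 and the 35 splits are too few to exclude chance. Each other split within scans also put arrays that are nearly alike into different groups. The tests hold only as far as the arrays, or for the last count the 7 units, are independent.

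Of the tests weighed in the next paragraphs, those of quantile-normalized array positions and the counts of splits above were set before their results were seen, and all others only after. First, 17 of the 18 named genes were lower in M2, with a median log2 fold change of −0.43. A candidate explanation is the scaling to 1 percentile on M2 arrays whose bright signals are compressed. The median of the 18 genes lay at the percentile 43.2 of 10000 random sets of 18 probes of like brightness, whose own median was −0.41, so these genes as a set fell no further than other bright probes. PGK1 stayed lower in M2 after quantile normalization and cyclic loess (higher limma adjusted p of the 2 values 0.0153). The gene was taken up after these values had been seen, so they cannot decide the cause. Among 200 probes of like brightness PGK1 lay at the percentile 14.5. With alike arrays averaged it was at −0.87 and not called (limma adjusted p = 0.25). A lower level of the PGK1 transcript in M2 cells stays open. For all 17 genes that were lower the scaling and a true decrease were not separated.

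Second, 6 pairs of arrays were nearly alike. Sharing a scan is argued against as the cause, since other pairs of M0 arrays in scan 1 and the pair of M2 arrays in scan 2 differed by at least 5.19 times the lowest SD. That the alike arrays are repeats of 1 RNA preparation may hold but cannot be told apart from very even cultures. The highest SD of these pairs was 1.78 times that expected between 2 spots of a probe on 1 array, and the lowest 1.27 times. The expected SD came from 18 bright probes with an accession, most of them brighter than most of the probes compared. These ratios are therefore uncertain, and hybridisation noise between arrays of the same RNA was not measured. The labels call the preparations independent, and averaging the alike arrays left 1102 calls.

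Last, M0 replicates 1 and 3 lay towards M2: on a scale where the M0 arrays of scan 3 are at 0 and its M2 arrays at 1, over 2124 probes that rose at 2-fold or more in scan 3 alone, the M0 arrays of scan 1 were at 0.82, 0.27, 0.80 and 0.20 (replicates 1 to 4). Over 3155 probes that fell they were at 0.15, −0.38, 0.15 and −0.28. Exchanged labels are argued against by the falling probes alone, where the lowest M2 array was 0.417 above M0 replicates 1 and 3. The M2 arrays there spread from 0.57 to 1.01. On rising probes both M0 replicates lay within the range of the M2 arrays (0.74 to 1.23), so exchanged labels were not excluded. Overall brightness is argued against too, since at least 90.3% of the gap to replicates 2 and 4 was kept after quantile normalization. An admixture of M2 RNA would give 1 share for all probes; against replicates 2 and 4, the median share was at most 11.6% on 65 to 74 probes that rise over 8-fold and at least 54.7% on probes that fall, with 41.1% to 45.5% on those that rise 2-fold to 8-fold. The quartiles of the strongly rising and the falling probes were apart against replicate 2 (upper at most 31.5% and lower at least 40.9%) and overlapped against replicate 4 (upper 45.3% and lower 33.4%). With M2 replicate 3 as the assumed source, it cannot be told apart from a difference between cultures. Without M0 replicates 1 and 3, 8057 probes were called and 5011 at 2-fold or more, and no biological explanation was tested.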
